A study of Mus musculus with 6 samples.

How the data were processed

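Single-cell RNA was measured by droplet sequencing in 6 libraries, 2 from E18.5 tissue labelled VT, 2 from P14 SVZ and 2 from adult SVZ. The deposited matrices hold raw UMI counts for 28692 genes by 6794880 barcodes per library, before any choice of cells, made by the authors with Cell Ranger 3.0.2 on genome build mm10 per the submitters' processing notes. The annotation release and any filters on genes were not stated, so positions were taken from GENCODE M21, which gave a position for 95.1% of genes by name. Everything else was computed from these counts with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).

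A barcode was kept as a cell with at least the larger of 1000 UMIs and the 99th percentile divided by 10 of UMIs, taken among the 3000 highest barcodes of its library, at least 500 genes, and at most 15% mitochondrial UMIs. Doublets were scored by the share of simulated doublets among nearest neighbours, and the highest scores were removed at a rate of 0.8% per 1000 cells, which took 8.24%, 7.95%, 5.28%, 3.99%, 5.20% and 3.33% of cells in the order E18.5, P14 and adult. Cells of all libraries were log-normalised and clustered together on 2000 variable genes, 30 principal components and 20 nearest neighbours by the Leiden method at resolution 1.0, with no integration across libraries. Olig2, mitochondrial, haemoglobin and sex-linked genes were left out of the variable genes. Clusters were named by the mean standardised level of fixed marker lists (181 genes in 17 classes; Pclaf was matched under its older symbol 2810417H13Rik). A name needed a leading score of at least 0.5 and at least 3 markers above 20 CPM. A cluster stayed unnamed where a second, unrelated class scored at least 0.75 and at least 0.6 of the leading score. It also stayed unnamed where more of its 10 leading genes were on the marker list of another class than on its own. A cluster whose leading genes were on no marker list could thus be named. Pairs of neighbouring classes, such as stem cells and astrocytes, were exempt from the rule on second scores. Marker genes took part in the clustering, so their differences between clusters are partly built in.

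Counts were summed per library over the cells of a class, with at least 20 cells per sum. The stem cell sums held 499 and 509 cells at E18.5, 399 and 177 at P14, and 120 and 214 in the adult. The neuroblast sums held 911 and 1078, 429 and 189, and 381 and 115, and the progenitor sums 1373 and 1490, 2292 and 1537, and 775 and 680. Sums were compared between ages by the edgeR quasi-likelihood F test with TMM scaling, its default filter for low counts and age as the only factor, all 6 libraries in 1 fit, and a Benjamini-Hochberg adjusted p under 0.05. Numbers of cells per class were compared in the same way without TMM. With 2 libraries per age no test of other splits was possible for the age comparisons.

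For Olig2, cells of a class with at least 1 Olig2 UMI were compared with the same number of cells with none, matched within library and cluster by the nearest UMI count, with library as a block and Olig2 left out of the test. Libraries with at least 20 detected cells entered. The stem cell sums held 244, 189, 115 and 41 detected cells; the adult libraries had 19 each and were left out. The progenitor sums held 483, 457, 800, 398, 197 and 152. A further F test asked whether the effect of detection was equal at all ages. Shares of cells with Olig2 were also computed with each cell thinned at random to 2000 UMIs. Endothelial cells and microglia were planned as the background. Detection of at least 1 UMI misses cells that hold little Olig2 RNA, so undetected cells are not cells without it.

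The 22 gene lists (352 genes, all found) covered embryonic radial glia, quiescent stem cells and astroglial maturation, cell cycle, dorsal patterning, lateral and ventral patterning, neurogenic genes, oligodendrocyte lineage, the Notch, Shh, receptor tyrosine kinase and FGF, BMP and Wnt pathways, cholesterol synthesis, antigen presentation and interferon, immediate early and dissociation genes, olfactory bulb interneuron subtypes, sex-linked genes, and carry-over from erythroid, oligodendrocyte, microglial, ependymal and vascular cells. Each list was tested by camera with the preset correlation of 0.01 and an adjusted p over the lists; camera with an estimated correlation and fry were run beside it. The lists, the tests, the cell filter and the rule for naming genes were fixed before the data were examined. The test of the age effect of Olig2 detection in dividing progenitors was not among these tests. The rule named up to 12 genes that rose and 12 that fell most per test, with an adjusted p under 0.05, at least 20 CPM and libraries that did not overlap (or the same direction in each pair), up to 2 members per direction of each list, and Olig2, Olig1, Gsx2, Dlx2, Pax6, Emx1, Egfr and Gfap always. Some genes picked by this rule, and a test of an explanation that used 1 of them, are not reported here. The text gives those of the others whose calls mostly held when libraries were left out, a choice made after the values were seen, as was the choice of Slc1a2 as a partner to Slc1a3. The thresholds of cluster naming were not among the choices fixed in advance.

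Exact intervals and floors at the 95% level cover counting error only, not the spread between animals. The fits were tested on simulated data: of 200 genes changed per comparison, 57% to 93% were recovered at 2-fold and 89% to 95% at 4-fold, with 12 to 26 false calls. The age fits gave 21 to 26 of these, a larger share of their calls than an adjusted p under 0.05 is meant to allow. Age calls near the threshold are therefore less sure than their adjusted p states.

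The alternatives tried were a replicate block, DESeq2 size factors, DESeq2, no filter for low counts, leaving out each library, cells with at least 2000 UMIs, at most 5% mitochondrial UMIs, no doublet removal, Leiden resolution 2.0, thinned cells, the same number of cells per library, and stem cells merged with astrocytes. For class shares the largest class was also left out. For the Olig2 comparison they were no depth matching, another order of matching, at least 2 Olig2 UMIs, and leaving out cells with any UMI of Pdgfra, Cspg4 or Sox10, genes of oligodendrocyte precursors. A minimum of 1000 UMIs in every library, the highest minimum in every library and a minimum of 10 detected cells were added after the data were seen, as were the alternatives for the age effect in progenitors.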

Results

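RNA of single cells from mouse brain was counted by droplet sequencing in 6 libraries, 2 at each of 3 ages. The embryonic pair came from E18.5 tissue given in the labels as VT, and the P14 and adult pairs came from the subventricular zone (SVZ), the stem cell niche beside the lateral ventricle. The series title names Olig2, a transcription factor of ventral neural progenitors and of the oligodendrocyte lineage, as the gene that sets apart some of the stem cells there. The libraries held 110767996 and 92726334 UMIs (distinct RNA molecules counted) at E18.5, 161123234 and 113514567 at P14, and 102491891 and 111635359 in the adult. Kept cells numbered 9446 and 9143 at E18.5, 6257 and 4792 at P14, and 6164 and 4021 in the adult. Their median depth was 6833 and 6041 UMIs per cell at E18.5, 11402 and 10484.5 at P14, and 7307 and 9651 in the adult. The labels do not say whether the replicates of an age were separate animals, so every p below measures only the spread between these libraries. Age and dissection cannot be told apart for E18.5, and the labels give no sex of the animals. Apart from tissue, age is the only factor that the labels give. A difference of strain or genotype between the animals of different ages, P14 and adult among them, therefore cannot be told apart from age. At 1 of 3 ages the libraries lay more than 10-fold apart in a sex-linked gene, so sex is not taken as even across libraries. That gene also set both E18.5 libraries far apart from both adult libraries in every tested class. Sex and age therefore cannot be told apart between E18.5 and adult. Unless another unit is named, changes are log2 fold changes ± SE from edgeR with adjusted p, and levels are CPM (the usual scaling of UMIs to a fixed library total) of the summed cells of a class in that fit, as mean ± SD over the 2 libraries of an age.

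The first comparison asked which cell classes each age held. At E18.5 the largest named class was striatal projection neurons, the inhibitory output neurons of the striatum, at 29.1% ± 0.85 of cells (SD, n = 2). Cortical-type interneurons made up 16.6% ± 3.33, dividing progenitors 15.4% ± 1.25 and neuroblasts, the migrating newborn neurons, 10.7% ± 1.52. At Leiden resolution 2.0 the E18.5 libraries held 2063 and 2309 neuroblasts, beside 911 and 1078, and more of them than of striatal projection neurons. No astrocyte, oligodendrocyte or choroid plexus cell was named in either E18.5 library, which by counting error alone allows shares of up to 0.0318% and 0.0328%. Names went to whole clusters, so these bounds do not cover such cells inside clusters of another name or none. Unnamed clusters held 20.2% ± 0.824 of E18.5 cells. Stem cell cluster 16 had astrocyte as its second class (score 0.36, beside 1.60), so astrocytes at E18.5 are not excluded. At P14 dividing progenitors were 34.4% ± 3.22 of cells, ciliated ependymal cells 19.7% ± 13.3 and oligodendrocyte precursors 9.06% ± 3.01. In the adult, oligodendrocytes were 19.1% ± 9.84, ependymal cells 17.3% ± 3.87, dividing progenitors 14.7% ± 3.07, astrocytes 7.36% ± 1.48 and microglia 3.51% ± 0.628. Cells of the neural stem cell class made up 5.43% ± 0.201 at E18.5, 5.04% ± 1.90 at P14 and 3.63% ± 2.39 in the adult. Postnatal cells of this class lay almost all in cluster 19 (574 of 576 at P14 and 332 of 334 in the adult), which scored 1.55 for stem cell and 1.34 for astrocyte markers and had 0 stem cell markers among its 10 leading genes, so astrocytes within it are not excluded. These shares rest on cells above a UMI minimum set per library, which was 3195.3 and 2583.9 at E18.5, 6409.2 and 5574.6 at P14, and 3965.3 and 5832.8 in the adult. With a minimum of 1000 UMIs in every library, added after the data were seen, P14 neuroblasts were 21.5% ± 2.21 of cells, dividing progenitors 20.8% ± 2.27 and the stem cell class 11.2% ± 0.681, while adult astrocytes were 19.5% ± 5.93, oligodendrocytes 14.5% ± 6.78, neuroblasts 11.8% ± 3.01 and dividing progenitors 8.37% ± 0.998. From E18.5 to P14, 10 of 13 classes changed, 7 upwards and 3 downwards. Oligodendrocyte precursors rose by 8.60 ± 0.61 (adjusted p = 0.000632), endothelial cells by 3.68 ± 0.42 (0.00267), microglia by 6.50 ± 1.10 (0.00617) and dividing progenitors by 1.16 ± 0.40 (0.0465), a call lost without any 1 of the 6 libraries (0.0727 to 0.189) and with the 1000 UMI minimum (0.50 ± 0.31, 0.164). The E18.5 libraries held 2 and 2 oligodendrocyte precursors and 0 and 2 microglia, beside 43 and 49 endothelial cells. The sizes of the rises of oligodendrocyte precursors and microglia therefore rest on very few E18.5 cells. Cortical-type interneurons changed by −6.31 ± 1.19 (0.00804) and excitatory neurons by −2.66 ± 0.54 (0.00948). The stem cell class differed by −0.11 ± 0.64 (0.873) and neuroblasts by −0.99 ± 0.58 (0.165). The 1000 UMI minimum turned both directions, to 1.04 ± 0.58 (0.147) and 1.02 ± 0.35 (0.0515), while at Leiden resolution 2.0 neuroblasts fell by 2.14 ± 0.60 (0.0199). Without P14 replicate 2 only 6 classes passed. Between P14 and adult edgeR called 0 of 13 classes; 3 had an unadjusted p under 0.05, namely dividing progenitors (−1.22 ± 0.40), oligodendrocytes (2.57 ± 0.62) and striatal projection neurons (4.06 ± 1.55), whose adult cells numbered 37 in replicate 1 and 410 in replicate 2. Between E18.5 and adult 8 classes changed, 6 upwards and 2 downwards.

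**Figure D1:**
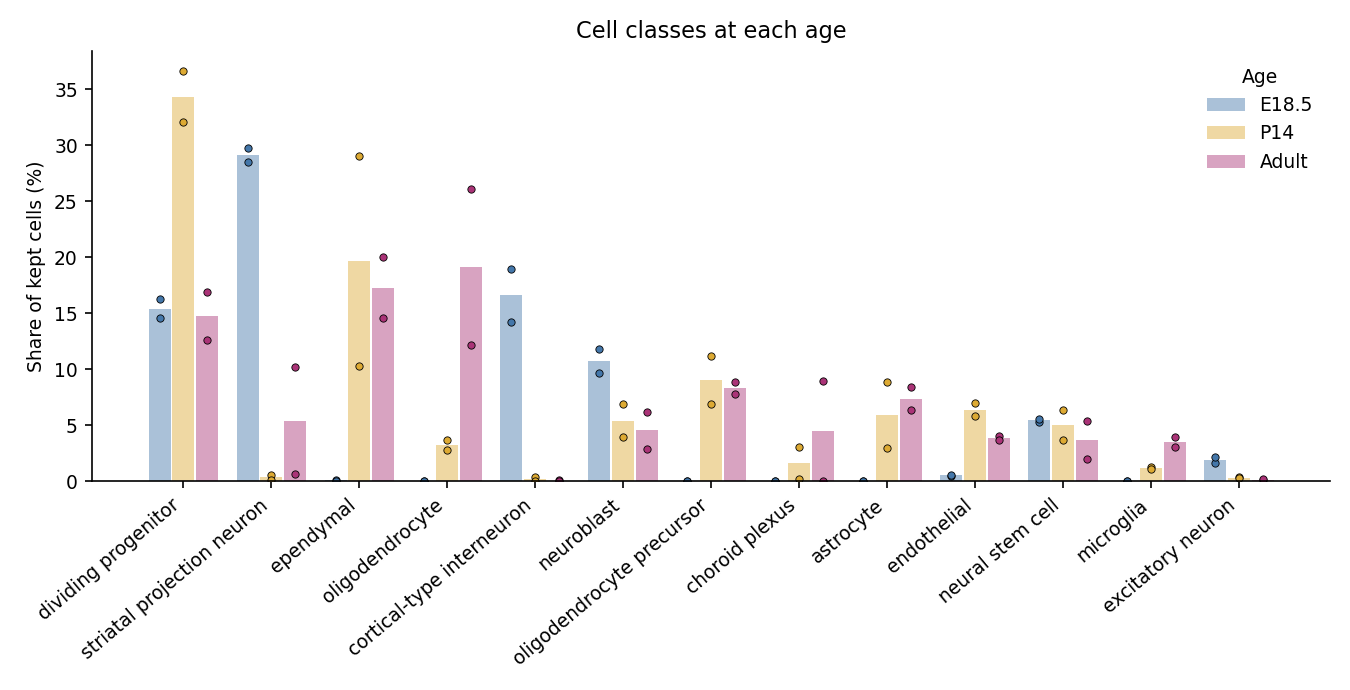
Share of kept cells (%) in each named cell class, with 1 point per library and a bar at the mean of the 2 libraries of each age. Dividing progenitors stand highest at P14 (34.4%), striatal projection neurons at E18.5 (29.1%) and oligodendrocytes in the adult (19.1%).

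The second comparison followed Olig2 (ENSMUSG00000039830) itself, which lies on the plus strand of mm10 chromosome 16 from 91225457 to 91228677 and holds its whole coding sequence, 91226400 to 91227368, in exon 2 of its single annotated transcript. Olig2 was left out of the genes used to cluster and name cells. In the stem cell class, 43.2% ± 8.32 of E18.5 cells, 26.1% ± 4.18 of P14 cells and 12.4% ± 4.91 of adult cells held at least 1 Olig2 UMI (SD, n = 2). With a minimum of 1000 UMIs in every library, which admits shallower cells, the shares were 40.2% ± 6.86, 14.1% ± 2.65 and 7.74% ± 4.48. In endothelial cells, planned as the background together with microglia, the shares were 3.34% ± 1.85, 2.30% ± 0.28 and 6.34% ± 1.55. Microglia stood higher at P14, at 9.20% ± 3.95 and 2.74% ± 2.10 in the adult, as did ependymal cells, at 10.5% ± 5.95 and 4.99% ± 0.28. Median depths in stem cells were 9118 and 8170 UMIs at E18.5, 9067 and 7975 at P14 and 5174 and 7744 in the adult. In endothelial cells they were 12079 and 11063, 11634.5 and 10773, and 6973 and 7986. With every cell thinned to 2000 UMIs the stem cell shares were 18.98% ± 3.77, 10.4% ± 1.19 and 5.94% ± 5.75, and the endothelial shares 0.0%, 0.42% ± 0.59 and 1.55% ± 1.23. Among dividing progenitors the shares were 35.3% ± 6.43, 30.4% ± 6.37 and 23.9% ± 2.17. Neuroblasts held Olig2 in 2.11% ± 0.03, 5.52% ± 1.08 and 0.92% ± 1.30 of cells, and in 0.86% ± 0.04, 1.64% ± 0.67 and 0.13% ± 0.18 when thinned to 2000 UMIs. Oligodendrocyte precursors were nearly all positive, at 97.0% ± 2.09 at P14 and 99.6% ± 0.16 in the adult, and astrocytes stood at 24.4% ± 0.47 and 20.7% ± 3.16. By unscaled CPM, stem cells held 110 ± 10.1 at E18.5, 60.7 ± 4.12 at P14 and 63.3 ± 69.5 in the adult, where the 2 libraries read 112.52 and 14.17. Microglia held 31.9 ± 6.46 at P14 and 4.19 ± 2.56 in the adult, and endothelial cells 2.24 ± 0.30 and 11.1 ± 1.70. Barcodes with at most 100 UMIs, which stand for free RNA, held 23.0, 53.3 and 62.9 from E18.5 to adult. Free RNA is therefore not excluded as part of the postnatal stem cell levels. In the fits across genes Olig2 in stem cells differed by −0.77 ± 0.43 from E18.5 to P14 (adjusted p = 0.211) and by −1.17 ± 0.50 from E18.5 to adult (0.0908), neither past the threshold; the latter was −2.87 and past the threshold without adult replicate 1, and 0.005 without adult replicate 2. In dividing progenitors Olig2 fell by 0.57 ± 0.18 from E18.5 to P14 (0.0396); the call was lost without E18.5 replicate 1 (0.198), E18.5 replicate 2 (0.106) or P14 replicate 2 (0.220).

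**Figure D2:**
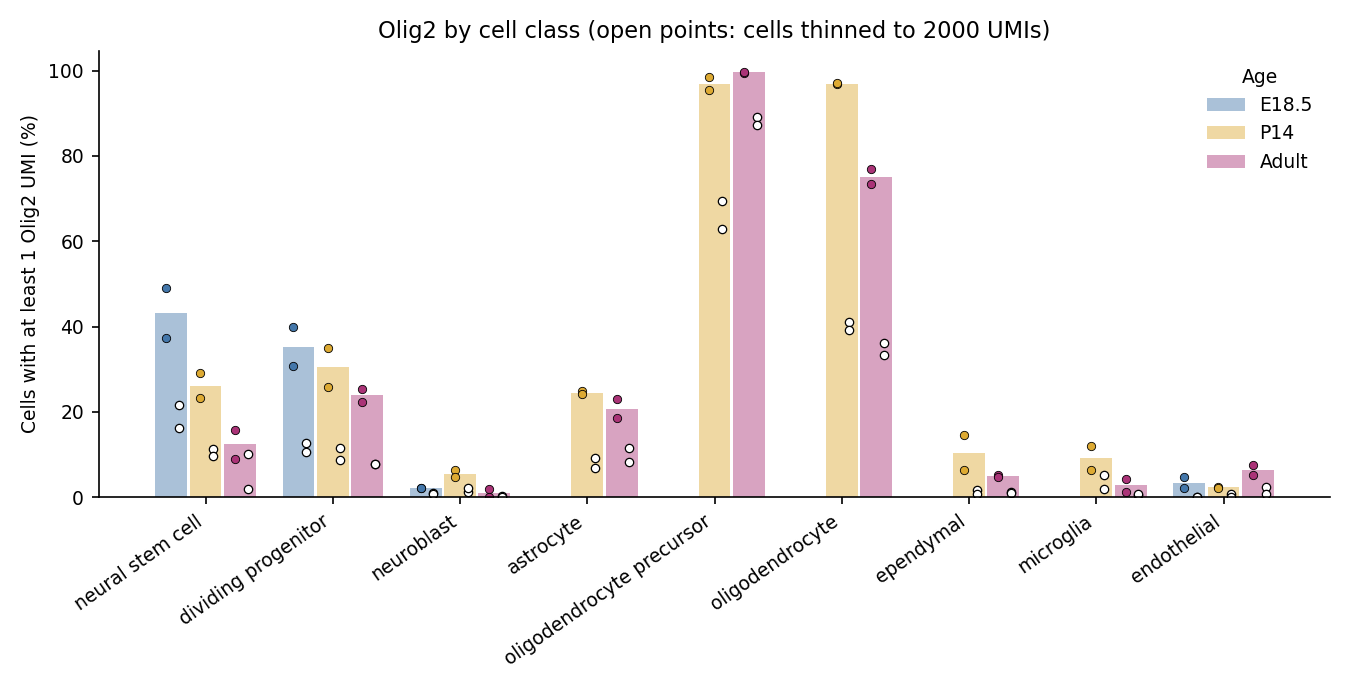
Share of cells (%) with at least 1 Olig2 UMI by cell class and age; filled points are libraries at full depth, open points the same libraries with every cell thinned to 2000 UMIs, and bars the full-depth mean. Stem cells go from 43.2% at E18.5 to 12.4% in the adult, against 3.34% and 6.34% in endothelial cells. Microglia, the other planned background, stand at 9.20% at P14 and 2.74% in the adult.

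The third comparison asked what distinguished stem cells in which Olig2 RNA was detected from those in which it was not. Cells with at least 1 Olig2 UMI were summed and set against as many undetected cells of the same library and cluster with matched depth; only the 4 libraries of E18.5 and P14 had the 20 detected cells required. The partner gene Olig1, which lies beside Olig2 and acts in the same lineage, stood at 204 ± 48.9 CPM in detected and 37.7 ± 14.4 in undetected cells (2.65 ± 0.14, adjusted p = 5.85e-13, higher in 4 of 4 pairs). The epidermal growth factor receptor Egfr, a marker of activated stem cells, rose by 2.10 ± 0.16 (3.49e-09). Draxin, a secreted axon guidance protein, rose by 1.99 ± 0.23, the creatine synthesis enzyme Gatm by 1.49 ± 0.19, and Traf4, Lrrfip1, Adrbk2 and Tril by 1.27 to 1.31. Lower in detected cells were Hs3st1, a heparan sulphate sulphotransferase (−1.95 ± 0.16), Rgs6, a regulator of G protein signalling (−1.73 ± 0.23), Urah, Chil1, and Hopx (−1.57 ± 0.22), a homeobox gene of radial glia and quiescent stem cells. Thbs4, a secreted glycoprotein of adult SVZ stem cells, changed by −1.13 ± 0.19. Pax6, a dorsal patterning factor, fell from 155 ± 58.0 to 81.3 ± 34.7 CPM (−0.92 ± 0.13, lower in 4 of 4 pairs).

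Of the fixed gene lists, lateral and ventral patterning stood higher in Olig2-detected stem cells, with 3 of 14 measured members up and 1 down (5 and 1 adjusted over the list alone; adjusted p = 3.92e-09, or adjusted p = 0.0744 with an estimated correlation). The oligodendrocyte lineage list had 4 of 9 members up and 0 down (5 and 1 over the list alone; 1.27e-07, or adjusted p = 0.214 with an estimated correlation). Among neurogenic genes 5 of 23 rose and 1 fell (0.00622, or adjusted p = 0.214 with an estimated correlation). Those that rose included the Notch ligand Dll1 (1.95 ± 0.29) and Hes6 (0.98 ± 0.15), and Btg1 changed by −0.56 ± 0.10. The list of quiescent stem cell and astroglial maturation genes stood lower, with 1 of 29 members up and 11 down (2 and 16 over the list alone; 1.43e-12, or adjusted p = 0.214 with an estimated correlation). Of 26 cell cycle genes 2 rose and 0 fell (5 over the list alone; 1.62e-05, or adjusted p = 0.401 with an estimated correlation), Ccnd1, the cyclin of the G1 phase, by 1.05 ± 0.14. Receptor tyrosine kinase genes had 3 of 15 up and 1 down (0.000432, or adjusted p = 0.214 with an estimated correlation), with Fgfr2 at −0.62 ± 0.12. In the Wnt list 0 of 12 rose and 4 fell (0.128, with a median above 0 and a mean and test below it), among them the Wnt antagonist Sfrp1 (−0.61 ± 0.09). Of the carry-over lists, haemoglobin RNA had 3 of 3 measured genes lower in detected cells (2.82e-34, or adjusted p = 0.0744 with an estimated correlation), myelin 2 of 3 higher (0.00272, or adjusted p = 0.305), ependymal 1 of 7 lower (0.00078, or adjusted p = 0.214), vascular 1 of 3 lower (0.0372, or adjusted p = 0.327), and the single measured microglial gene was lower. In all, edgeR called 478 of 10023 genes, 192 higher and 286 lower. With at most 5% mitochondrial UMIs it called 71 and at Leiden resolution 2.0 126, and DESeq2 called 146. The count was 784 without E18.5 replicate 1, 284 without E18.5 replicate 2, 184 without P14 replicate 1 and 236 without P14 replicate 2.

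Among dividing progenitors, 6 libraries entered the same comparison. After matching, detected cells still had a higher median depth in E18.5 replicate 1 (12865 against 11956 UMIs) and P14 replicate 1 (13342.5 against 12782.5). The gap was smaller in E18.5 replicate 2 and adult replicate 2, and turned slightly the other way in P14 replicate 2 and adult replicate 1. Olig1 stood at 82.1 ± 34.1 CPM in detected and 14.3 ± 9.27 in undetected cells (2.58 ± 0.22, adjusted p = 4.86e-07, n = 6). Gsx1, a homeobox gene of ventral progenitors, rose by 1.30 ± 0.06 (1.05e-09), Egfr by 1.11 ± 0.08 (1.04e-07) and Mfge8, a bridging protein of phagocytosis, by 0.99 ± 0.08. Nkx2-1, which patterns the medial ganglionic eminence and its derivatives, rose by 1.35 ± 0.13 and Ramp1 by 0.99 ± 0.16, each higher in 6 of 6 pairs. Lower in detected progenitors were Sp8, a factor of olfactory bulb interneurons (−1.09 ± 0.16), the microtubule genes Stmn2 (−0.88 ± 0.07) and Tubb3 (−0.71 ± 0.05), the guidance receptor Robo2 (−0.87 ± 0.15), Tiam2 (−0.79 ± 0.08) and Igfbpl1 (−0.74 ± 0.07). Dlx5 (−0.73 ± 0.05), Sp9 (−0.63 ± 0.05), Dlx2 (−0.34 ± 0.04) and Gad1 (−0.66 ± 0.08), genes of inhibitory neuron fate, were lower in 6 of 6 pairs.

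By list, 21 of 25 neurogenic genes fell and 3 rose in Olig2-detected progenitors, by the same counts over the list alone (adjusted p = 6.83e-46); this call held with an estimated correlation (0.0341). Of 14 oligodendrocyte lineage genes 9 rose (11 over the list alone; 1.06e-13, and 0.0345 with an estimated correlation), and of 15 receptor tyrosine kinase genes 9 rose and 1 fell (10 and 1 over the list alone; 9.13e-12, and 0.0345), with the FGF target Etv4 at 1.88 ± 0.21. Notch pathway genes had 10 of 15 up and 0 down (12 over the list alone; 1.39e-11, or adjusted p = 0.11 with an estimated correlation), with Dll1 at 0.79 ± 0.06. Lateral and ventral patterning had 7 of 15 up and 3 down (1.76e-08, or adjusted p = 0.112 with an estimated correlation). In the Shh list 3 of 10 rose (0.000931, or adjusted p = 0.229 with an estimated correlation), among them the co-receptor Gas1 (0.75 ± 0.06) and the receptor Ptch1 (0.72 ± 0.08). Of 30 cell cycle genes 1 rose and 13 fell (0.000132, or adjusted p = 0.182 with an estimated correlation); the riser was Ccnd1 (0.72 ± 0.07), and Ccnd2 changed by −0.36 ± 0.03. The astroglial list had 7 of 29 up and 3 down (0.000438, or adjusted p = 0.441 with an estimated correlation). Of the carry-over lists, myelin had 2 of 8 genes higher (0.176), haemoglobin 1 of 5 higher (0.117), and ependymal 0 of 8, vascular 0 of 6 and microglial 0 of 2 past the threshold. In all, 1520 of 11612 genes were called, 792 higher and 728 lower, and without P14 replicate 1 the count was 893. It was 774 with at most 5% mitochondrial UMIs, 708 at Leiden resolution 2.0, 609 by DESeq2 and 4200 without depth matching.

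**Figure D3:**
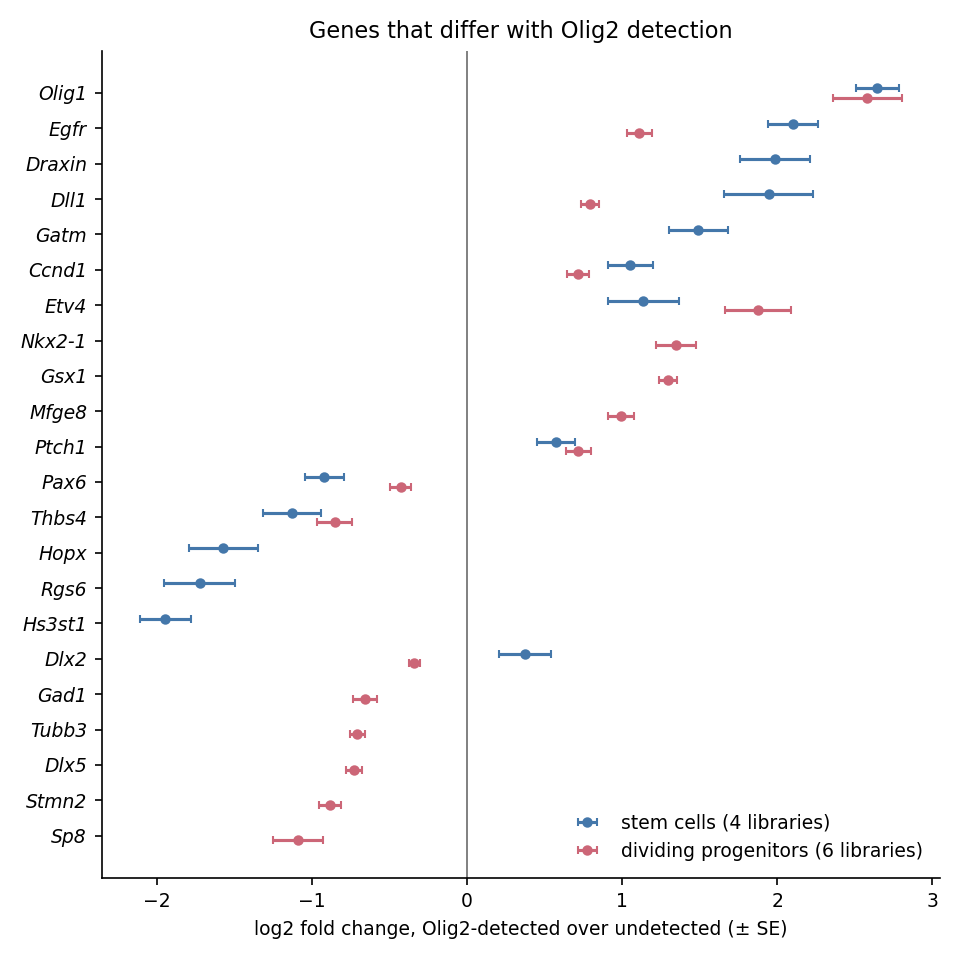
Log2 fold change (Olig2-detected over depth-matched undetected cells, ± SE) of named genes in stem cells (4 libraries) and dividing progenitors (6 libraries), each shown in the classes where the naming rule picked it. Olig1 and Egfr lie right of 0 in both classes, and Sp8, Stmn2 and Dlx5 lie left of 0 in progenitors.

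The test of an unequal effect of detection across ages passed for 37 genes in stem cells and 101 in dividing progenitors. For progenitors this test was not among those fixed before the data were examined. Both counts moved strongly without the low-count filter, as given under processing below. So did the stem cell count with at least 10 detected cells and the progenitor count without depth matching. In progenitors Olig1 differed by 4.44 at E18.5, 2.12 at P14 and 1.53 in the adult (adjusted p = 3.46e-06), Ramp1 by 3.47, 0.92 and 0.51 (0.000333), and Sp8 by −2.01, −0.65 and −0.72 (8.29e-05). In stem cells Gfap, the intermediate filament of astroglia, differed by 0.76 at E18.5 and −1.91 at P14 (3.96e-05), and Lgals3, which encodes galectin 3, by −1.84 and −0.44 (0.00147).

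The fourth comparison set the stem cell class at P14 against E18.5. E18.5 cells of the class lay mostly in cluster 16 and postnatal ones in cluster 19, and Thbs4, Fabp7, Tnc and Gfap were among its naming markers, so the changes below include those that separated the clusters. At P14 the cells held markers of quiescent and astroglial cells that were near absent at E18.5. Thbs4 counted 985 UMIs at P14 against 2 at E18.5 over both libraries of each, a pooled ratio of 725 (95% exact interval 200 to 6000). The gap junction gene Gjb6 counted 381 against 1, a ratio of 561 (100 to 22200). Notum, a secreted Wnt antagonist, rose from 1.10 ± 0.723 to 150 ± 16.1 CPM (7.09 ± 0.31, adjusted p = 2.19e-08), the neurotensin receptor Ntsr2 from 4.38 ± 1.63 to 358 ± 7.26 (6.32 ± 0.28) and Gpr37l1, an astroglial receptor, from 7.79 ± 0.399 to 348 ± 36.4 (5.47 ± 0.21). Gfap rose by 3.69 ± 0.20, the complement gene C4b by 5.35 ± 0.28, and Cmya5, Gpld1, Urah, Fam107a and Prex2 by 4.84 to 6.94. The brain fatty acid binding protein Fabp7, a radial glial marker, fell from 24200 ± 3620 to 3220 ± 337 CPM (−2.91 ± 0.18, adjusted p = 1.65e-07). The extracellular matrix gene Tnc fell from 178 ± 8.87 to 21.8 ± 1.85 (−3.01 ± 0.17), Igfbp2, which binds insulin-like growth factors, by 4.69 ± 0.35, the imprinted genes H19 by 4.65 ± 0.28 and Mest by 3.03 ± 0.21, the FGF carrier Fgfbp3 by 3.53 ± 0.21, and Fstl5, Sfrp2 and Islr2 by 2.91 to 3.24. Of the genes followed in every comparison, Pax6 rose by 1.13 ± 0.16. Egfr rose by 1.33 ± 0.25, a call lost without P14 replicate 1 (0.0512), and Gsx2, a ventral homeobox gene, changed by −1.09 ± 0.31, lost without E18.5 replicate 2 (0.138) or P14 replicate 2 (0.0818).

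Of 29 genes of quiescent stem cells and astroglial maturation, 26 rose and 1 fell (28 and 1 adjusted over the list alone), the one call of this comparison that held with an estimated correlation (adjusted p = 4.31e-36, and 0.0258). The member that fell was the folate enzyme Aldh1l1 (−2.13 ± 0.19). Of 19 embryonic radial glia genes 11 fell and 1 rose (13 and 1 over the list alone; 1.26e-10, or adjusted p = 0.114 with an estimated correlation). Of 30 cell cycle genes 20 fell and 0 rose (9.26e-12, or adjusted p = 0.114 with an estimated correlation), Ccnd1 by 2.01 ± 0.24. Cholesterol synthesis had 12 of 20 genes down and 0 up (16 over the list alone; 1.04e-07, or adjusted p = 0.114 with an estimated correlation), with Acat2 at −1.92 ± 0.16 and Fdps at −1.35 ± 0.16. Higher at P14 were oligodendrocyte lineage genes (12 of 16 up, 0 down; 1.61e-07, or adjusted p = 0.172 with an estimated correlation), the antigen presentation and interferon list (7 of 15 up, 0 down; 0.000111, or adjusted p = 0.114), immediate early and dissociation genes (12 of 20 up, 0 down; 1.91e-06, or adjusted p = 0.17), with Junb at 2.88 ± 0.26, and the Wnt pathway (7 of 14 up, 2 down; 0.00188, or adjusted p = 0.17). Not past the threshold were dorsal patterning (4 of 12 up, 3 down; 0.739), lateral and ventral patterning (3 of 16 up, 7 down; 0.38), neurogenic genes (4 of 25 up, 8 down; 0.192), with Gadd45g up by 3.23 ± 0.17, the Notch pathway (1 of 16 up, 4 down; 0.0793), with its target Hes5 at −1.94 ± 0.28, the Shh pathway (1 of 12 up, 1 down; 0.822, with a median above 0 and a mean and test below it), receptor tyrosine kinases (3 of 17 up, 2 down; 0.448), the BMP pathway (4 of 15 up, 1 down; 0.0509), with Id2 up by 2.71 ± 0.25, and olfactory bulb interneuron subtypes (3 of 18 up, 6 down; 0.0521). Sex-linked genes had 1 of 6 up and 1 down (0.822).

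Markers of other cell types moved with these groups. Of 8 myelin genes 7 rose (4.33e-09, or adjusted p = 0.17 with an estimated correlation), Mbp, the myelin basic protein, from 3.02 ± 0.63 to 212 ± 238 CPM, beside 700 CPM in P14 barcodes with at most 100 UMIs, which stand for free RNA. Of 8 ependymal genes 5 rose (0.000609, or adjusted p = 0.114), of 6 vascular genes 5 rose (0.01, or adjusted p = 0.17), haemoglobin had 1 of 5 lower (0.192), and of 2 measured microglial genes 1 rose and 1 fell. In all, 3167 of 12061 genes changed, 1758 up and 1409 down. The count was 1782 without E18.5 replicate 1, 1817 without E18.5 replicate 2, 1543 without P14 replicate 1 and 2076 without P14 replicate 2.

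**Figure D4:**
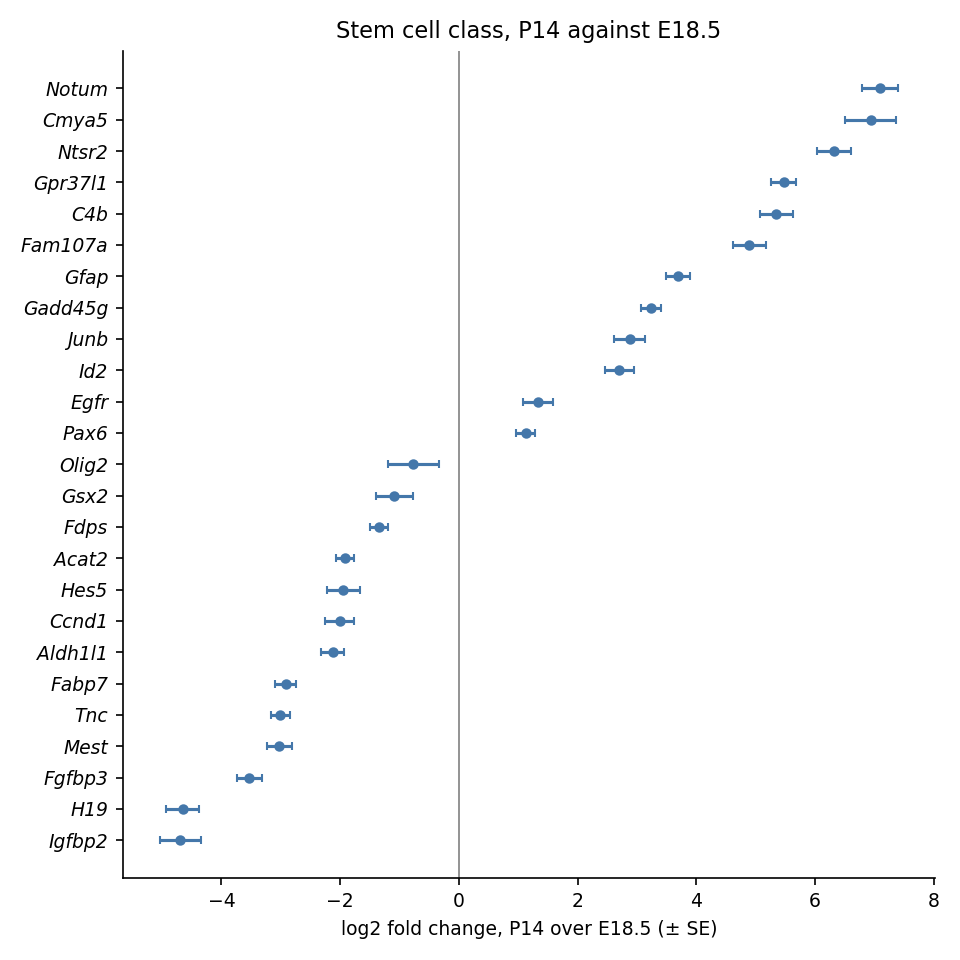
Log2 fold change (P14 over E18.5, ± SE) of named genes in the stem cell class, 2 libraries per age. Of the genes drawn, Notum (7.09) lies at the top and Igfbp2 (−4.69) at the bottom. Thbs4 and Gjb6, given in the text as pooled ratios, are not drawn.

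The fifth comparison set adult against P14 stem cells. The glutamate transporter Slc1a3 (GLAST, on mm10 chromosome 15 from 8634124 to 8710764) fell from 3290 ± 43.2 to 59.1 ± 13.3 CPM (−5.75 ± 0.19, adjusted p = 1.52e-09). The matrix protein Sparc fell from 1330 ± 112 to 329 ± 34.6 CPM (−2.01 ± 0.16), and Perp, Pdlim2, Arxes1, Cd200 and Ly6h by 1.83 to 2.67. Ly6h stood at 47.2 ± 0.496 CPM at P14 and 13.8 ± 1.95 in the adult. Barcodes with at most 100 UMIs held it at 279 and 188 CPM, so free RNA is not excluded for its fall. Fabp7 fell by 1.16 ± 0.17 and Ptn, a growth factor of radial glia, by 1.13 ± 0.15. Ecel1, a membrane peptidase, rose from 5.83 ± 1.44 to 69.9 ± 27.9 CPM (3.39 ± 0.33). The cytokine inhibitor Socs3 rose by 2.76 ± 0.24 (9.15e-05), the RNA-binding protein Zfp36 by 2.73 ± 0.28, Irf1, a factor of the interferon response, by 2.62 ± 0.29, Maff by 3.14 ± 0.39, Nr4a3 by 2.83 ± 0.40 and the chaperone Hspa1a by 3.31 ± 0.44. The zinc-binding Mt1 rose by 1.10 ± 0.15. Of the genes followed in every comparison, Egfr differed by 0.63 ± 0.26 (0.203), not past the threshold, and Gsx2 rose from 13.9 ± 9.43 to 40.7 ± 2.91 CPM (1.34 ± 0.34, 0.0442), a call lost without any library but P14 replicate 1 (0.0532 to 0.158). Hes5 rose by 1.35 ± 0.27 (0.0148), lost without P14 replicate 1 (0.165) or replicate 2 (0.0526).

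Of 20 immediate early and dissociation genes 17 rose and 0 fell (18 over the list alone; adjusted p = 5.64e-34, or adjusted p = 0.141 with an estimated correlation). The interferon list had 2 of 15 up (6 over the list alone; 4.29e-05, or adjusted p = 0.221 with an estimated correlation) and the BMP pathway 2 of 15 up (4 over the list alone; 0.0201, or adjusted p = 0.458). Embryonic radial glia genes had 4 of 19 down (7 over the list alone, and 1 up; 0.00393, or adjusted p = 0.336 with an estimated correlation), cell cycle genes 1 of 30 down (0.00727, or adjusted p = 0.221) and cholesterol synthesis 4 of 20 down (0.01, or adjusted p = 0.381). The astroglial list had 4 of 29 up and 4 down (0.325), and sex-linked genes 1 of 6 up and 1 down (0.231). No list call of this comparison held with an estimated correlation. Of the carry-over lists, myelin had 3 of 8 genes higher (7.45e-07, or adjusted p = 0.221 with an estimated correlation), with Mal up by 2.26 ± 0.33, and ependymal 1 of 8 lower (0.00365, or adjusted p = 0.221), namely Fam183b (−2.10 ± 0.24). Vascular genes had 1 of 6 higher (0.875), haemoglobin 1 of 5 higher (0.69) and microglial genes 1 of 2 higher. In all, 481 genes changed, 253 up and 228 down; the count was 834 with a replicate block, 104 without P14 replicate 1 and 174 without P14 replicate 2.

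Over the whole interval from E18.5 to adult, 4005 genes changed in the stem cell class, 2135 up and 1870 down. Ntsr2 rose by 7.31 ± 0.29, Gpr37l1 by 6.52 ± 0.22, the urea cycle enzyme Ass1 by 6.78 ± 0.34 and the signalling inhibitor Ppp1r1b by 7.25 ± 0.50. Fabp7 fell by 4.08 ± 0.19, Slc1a3 by 4.49 ± 0.19, the urea transporter Slc14a2 by 4.46 ± 0.27 and Bcl11b, a factor of striatal neurons, by 3.45 ± 0.51. Ppp1r1b and Bcl11b were also naming markers of striatal projection neurons. No carry-over list covered neurons, so carry-over from those cells is not excluded for these genes. Egfr rose by 1.96 ± 0.27. With an estimated correlation 4 list calls held, namely the astroglial list (24 of 29 up, 2 down; 0.0393), cell cycle (22 of 30 down; 0.0393), interferon (13 of 15 up; 0.0409) and immediate early genes (18 of 20 up; 0.0409). Of the carry-over lists, myelin had 8 of 8 genes higher (8.27e-15, or adjusted p = 0.107 with an estimated correlation), vascular 4 of 6 higher and 1 lower (0.035, or adjusted p = 0.255), ependymal 3 of 8 higher and 2 lower (0.303), haemoglobin 1 of 5 higher and 1 lower (0.396), and of 2 measured microglial genes 1 rose and 1 fell. The count was 2567 without E18.5 replicate 1 and 2457 without E18.5 replicate 2.

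The sixth comparison followed neuroblasts, which lay mostly in cluster 9 at E18.5 and in cluster 12 later. Cluster 31, with Epha5 and Nr2f2 among its leading genes, held 397 of 1989 neuroblasts at E18.5, 5 of 618 at P14 and 0 of 496 in the adult. The changes below, those of Epha5 and Nr2f2 among them, include that difference in make-up. From E18.5 to P14 the genes that rose most were those of glia. The apolipoprotein Apoe rose from 47.9 ± 2.62 to 651 ± 13.4 CPM (3.76 ± 0.14, adjusted p = 6.32e-09), beside 9380 CPM in P14 barcodes with at most 100 UMIs. Clu rose by 4.62 ± 0.23 and Aldoc by 4.40 ± 0.29. The ephrin receptor Epha5 fell by 4.12 ± 0.19, the neurofilament Nefm by 3.18 ± 0.21, Nr2f2, a factor of caudal interneurons, by 4.55 ± 0.38 and Six3, a forebrain homeobox gene, by 2.55 ± 0.23. Pax6 rose by 1.40 ± 0.17. The astroglial list had 23 of 27 genes up and 0 down (24 over the list alone; 2.5e-78, and 0.00992 with an estimated correlation), cell cycle genes 18 of 30 up (20 over the list alone; 1.28e-11, or adjusted p = 0.144 with an estimated correlation), with Cdk1 at 2.29 ± 0.28, and 0 of 25 neurogenic genes passed (0.504). The P14 sums held 429 and 189 neuroblasts, beside 2910 and 2130 with a minimum of 1000 UMIs in every library. At E18.5 they held 911 and 1078, beside 983 and 1153. RNA-rich P14 neuroblasts were therefore set against nearly all E18.5 ones, which bears on the cell cycle rise as well. Myelin had 7 of 8 genes up (6.55e-17, or adjusted p = 0.144 with an estimated correlation) and ependymal 7 of 8 up (2.66e-13, or adjusted p = 0.144). Free RNA from other cells is therefore not excluded for the rises of Apoe, Clu, Aldoc and the astroglial list. In all, 1318 of 11161 genes changed, 775 up and 543 down. The count was 452 and 568 without E18.5 replicates 1 and 2, and 450 and 786 without P14 replicates 1 and 2.

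Between P14 and adult, 46 genes changed in neuroblasts, 21 up and 25 down. With a replicate block the count was 156; deviations of equally numbered libraries correlated by 0.108 to 0.231 between ages in this class. Slc1a3 fell by 4.13 ± 0.32, Hddc3, a hydrolase, by 2.95 ± 0.30, Bambi, a decoy receptor of the BMP pathway, by 2.31 ± 0.31, Fabp7 by 2.10 ± 0.25 and Ina, an intermediate filament of neurons, by 1.40 ± 0.18. In barcodes with at most 100 UMIs Slc1a3 stood at 418 CPM at P14 and 40.5 in the adult, and Fabp7 at 855 and 225, beside 98.4 ± 22.0 and 6.83 ± 3.84, and 143 ± 28.1 and 36.5 ± 14.2, in neuroblasts, so free RNA is not excluded for these falls. The histone gene Hist1h2bc rose by 1.30 ± 0.18, beside 137 and 232 CPM in those barcodes. Of 30 cell cycle genes 1 fell (10 down and 1 up over the list alone; adjusted p = 2.11e-06, or adjusted p = 0.419 with an estimated correlation), and of 20 cholesterol synthesis genes 0 passed (6 up over the list alone; 3.99e-06, or adjusted p = 0.419). In the carry-over lists 0 genes passed; myelin had 4 of 8 up over the list alone (0.000235, or adjusted p = 0.456 with an estimated correlation), microglial 3 of 4 up (0.000235, or adjusted p = 0.419) and ependymal 1 of 8 up (0.00959, or adjusted p = 0.486). The count was 31 and 30 without E18.5 replicates 1 and 2, 23 without P14 replicate 1 and 125 without adult replicate 2.

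The seventh comparison followed dividing progenitors, which held the most cells of the tested classes. Of their clusters, number 17, with Slc1a3 among its leading genes and the stem cell class second by score, held 7 of 2863 cells at E18.5, 819 of 3829 at P14 and 164 of 1455 in the adult, so the changes below include that difference in make-up. From E18.5 to P14 Gpr37l1 rose from 0.505 ± 0.0371 to 61.8 ± 3.12 CPM (6.92 ± 0.27, adjusted p = 3.21e-06), the phospholipase Pla2g7 by 6.71 ± 0.34, Crym, a thyroid hormone binding protein, by 5.20 ± 0.53, Ntsr2 by 4.50 ± 0.19 and Thrsp, a regulator of lipid synthesis, by 4.26 ± 0.18. Egfr rose from 29.3 ± 2.49 to 86.7 ± 2.56 CPM (1.57 ± 0.12), Pax6 by 1.13 ± 0.12 and Gfap by 6.30 ± 0.47. P14 barcodes with at most 100 UMIs held Gfap at 60.4 CPM, above its 32.7 ± 12.6 in P14 progenitors, so free RNA is not excluded for Gfap. They held Egfr at 27.7 and Pax6 at 52.3, below the 86.7 and 155 CPM in P14 progenitors. The RNA-binding proteins Igf2bp1 and Igf2bp3, which mark fetal tissue, fell by 7.20 ± 0.22 and 3.23 ± 0.15. Isl1, a factor of striatal and cholinergic neurons, fell from 44.8 ± 0.526 to 0.654 ± 0.103 CPM (−6.04 ± 0.24), Slc18a2 by 3.44 ± 0.29, Grb10 by 2.86 ± 0.14 and Nkx2-1 by 2.37 ± 0.37. Dlx2 fell by 0.77 ± 0.15. The astroglial list had 28 of 29 genes up (1.67e-62, or adjusted p = 0.184 with an estimated correlation) and oligodendrocyte lineage genes 18 of 20 up (2.82e-13, or adjusted p = 0.236). Embryonic radial glia genes had 12 of 20 down and 3 up (1.48e-09, or adjusted p = 0.223 with an estimated correlation), lateral and ventral patterning 9 of 17 down and 3 up (1.58e-05, or adjusted p = 0.223) and cell cycle genes 19 of 30 down (22 over the list alone; 1.96e-06, or adjusted p = 0.223), Mki67 by 0.77 ± 0.11. Of the carry-over lists, ependymal had 8 of 8 genes higher, myelin 7 of 8, vascular 7 of 9 and microglial 5 of 9. In all, 4192 of 13775 genes changed, 2452 up and 1740 down. The count was 1932 and 2179 without E18.5 replicates 1 and 2, and 2523 and 2336 without P14 replicates 1 and 2.

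Between P14 and adult, 327 genes changed in dividing progenitors, 95 up and 232 down, and 579 with a replicate block. The count was far lower with thinned cells. It was higher by DESeq2, without the low-count filter, with at most 5% mitochondrial UMIs and with doublets put back, as given under processing below. Slc1a3 fell from 554 ± 25.9 to 9.65 ± 2.46 CPM (−5.84 ± 0.18, adjusted p = 2.38e-06), Ptn by 1.66 ± 0.13, Hddc3 by 2.70 ± 0.21, the Wnt antagonist Sfrp1 by 1.56 ± 0.15, the potassium channel Kcnk2 by 1.46 ± 0.11 and Eomes, a factor of excitatory precursors, by 2.42 ± 0.23. The astroglial list had 6 of 29 genes down (12 over the list alone; 8.81e-12, or adjusted p = 0.446 with an estimated correlation) and dorsal patterning 3 of 14 down (5 over the list alone; 5.1e-06, or adjusted p = 0.292). Immediate early genes had 5 of 20 up (11 over the list alone; 4.49e-10, or adjusted p = 0.414 with an estimated correlation). Among them Atf3 reached 18.3 ± 7.41 and Hspa1b 3.39 ± 0.0882 CPM, beside 285 and 51.7 CPM in adult barcodes with at most 100 UMIs, both calls lost without P14 replicate 1 (0.0677 and 0.0995) or adult replicate 1 (0.0708 and 0.0687). By carry-over list, myelin had 1 of 8 genes higher (0.000136, or adjusted p = 0.636), namely Mal (2.20 ± 0.36, lost without adult replicate 1, 0.0864), vascular 1 of 9 lower (0.362) and microglial, ependymal and haemoglobin 0 genes past the threshold (0.0342, 0.0838 and 0.098). The count was 113 without either E18.5 replicate, 58 and 69 without P14 replicates 1 and 2, and 33 without adult replicate 1. By unscaled CPM, Slc1a3 in astrocytes stood at 3880 ± 180 at P14 and 74.5 ± 8.51 in the adult, a 52.1-fold difference, while the related transporter Slc1a2 stood at 4590 and 5490. The astrocytes lay in cluster 22 at P14 (689 of 694) and in cluster 20 in the adult (766 of 772).

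**Figure D5:**
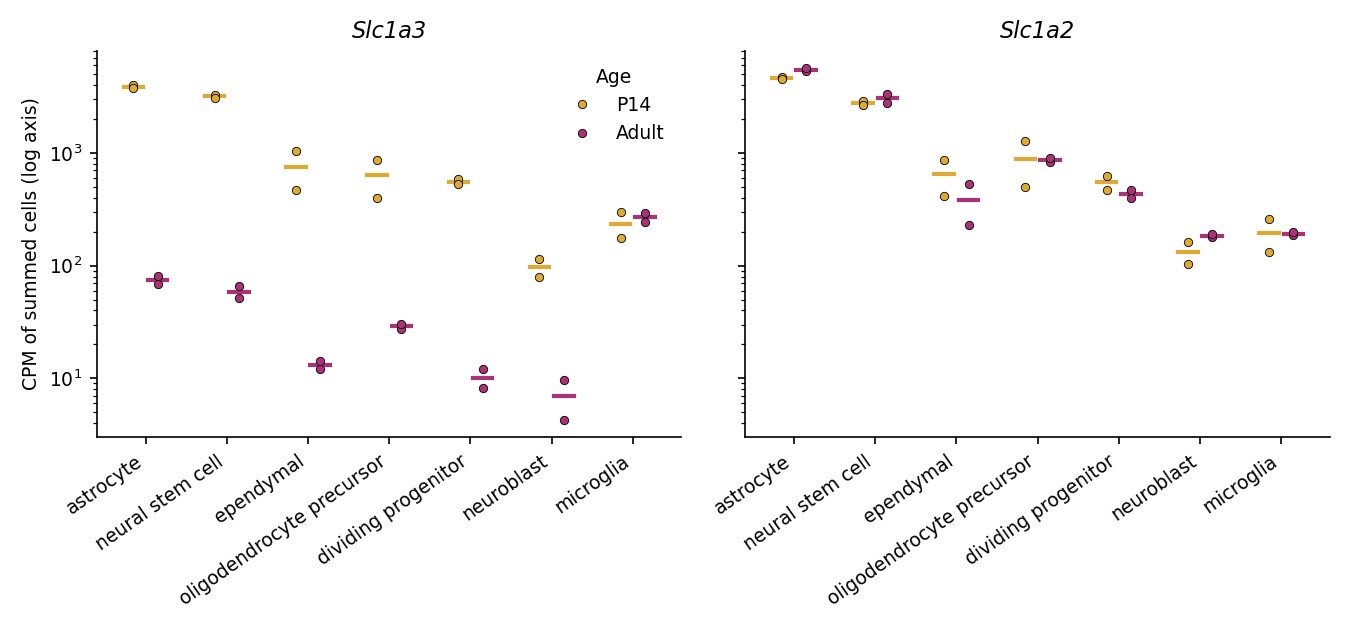
Unscaled CPM (log axis) of the glutamate transporters Slc1a3 and Slc1a2 by cell class at P14 and in the adult, with 1 point per library and a bar at the mean. In astrocytes Slc1a3 stands at 3880 and 74.5 CPM and Slc1a2 at 4590 and 5490.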

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

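All tests of explanations below were chosen after the result was seen, except the test of a strain stretch around Slc1a3, which was set before its result was seen. Groups of 2 libraries are too small to search for outlying samples, so none was searched for.

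The effect of Olig2 detection differed between ages, by a test of that difference, for several of the genes that the text names in that comparison. In dividing progenitors these were Olig1 (adjusted p = 3.46e-06), Sp8 (8.29e-05), Ramp1 (0.000333), Mfge8 (0.00155), Robo2 (0.00212), Tiam2 (0.00367), Igfbpl1 (0.0129), Egfr (0.0206) and Ccnd1 (0.0219). In stem cells they were Gfap (3.96e-05), Lgals3 (0.00147), Hes6 (0.00943) and Hba-a1 (0.0420). Relative to E18.5, a few genes stood on one side in every P14 library of a class and on the other side in every P14 library of another class; these differences between classes were not tested. Fabp7 fell in stem cells and stood at 0.76 in neuroblasts. Olig2 stood lower in P14 stem cells (adjusted p = 0.211), at 0.90 ± 0.40 in P14 neuroblasts (0.170), past the threshold in neither, and at −0.57 in P14 dividing progenitors; in neuroblasts it stood at 4.43 and 7.59 CPM, beside 23.0 and 53.3 in barcodes with at most 100 UMIs, so free RNA is not excluded there.

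The first pattern weighed was the fall of Slc1a3 from P14 to adult stem cells. Fewer astroglial cells in the adult class would have lowered the other astroglial genes as well, but the median change of the other 28 members of that list was −0.024 (quartiles −0.215 and 0.292), which argues against it. An allele that lowers Slc1a3 in every cell type is argued against by microglia, where the log2 ratio of adult to P14 was 0.196 (269 ± 37.1 CPM in the adult and 235 ± 86.5 at P14, SD, n = 2). A stretch of another strain around the gene stays open, since 0 of 35 genes within 10 Mb were called against 321 of 13295 elsewhere in dividing progenitors, an odds ratio of 0.0 with an upper bound of 4.52 (Fisher's exact test, p = 1). An allele that acts only in cells of astroglial descent, and age itself, also stay open and were not tested. A sex-linked gene set the P14 libraries apart, yet Slc1a3 stood at 3290 ± 43.2 CPM over both, which speaks against sex as the source but rests on 1 library.

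The second pattern was the rise of immediate early genes in adult stem cells. A response of all cells during handling of the adult tissue is argued against by astrocytes alone: the median log2 ratio was above 0.5 in 7 of 8 other classes but stood at −0.352 in astrocytes, with an upper quartile of 0.105 and medians from −1.132 to 0.309 over the pairings of single libraries. Astrocytes of each age lay almost all in a cluster of their own (689 of 694 cells in cluster 22 at P14, 766 of 772 in cluster 20 in the adult), so this ratio includes any difference between those clusters; oligodendrocytes and endothelial cells also lay mostly in separate clusters by age, with medians of 3.246 and 2.681. A response of most classes to handling was not excluded. Free RNA from other cells is argued against as the source of most of the rises, because in 13 of 17 genes that rose the smallest rise exceeded what free RNA could bring, taken as 22.9% of the highest adult level in barcodes with at most 100 UMIs; an earlier form of this bound was replaced after its result was seen. For the remaining 4, Atf3, Ier3, Hspa1a and Hspa1b, free RNA as the source stays open, and age stays open for the whole list, untested. In 17 of 17 genes the lowest adult library stood above both P14 libraries, which a sex-linked gene set apart. These genes had been picked because they rose between the same libraries, which a gene that followed sex would rarely do. The 17 of 17 was thus close to given and cannot decide on sex as the source.

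Exchanging detected and undetected sums within libraries gave 8 splits for stem cells and 32 for dividing progenitors. In progenitors 1 split, the real one, reached 1520 genes, and the highest other gave 171, which argues against a grouping by chance. In stem cells 1 split, the real one, reached 478 and the highest other gave 2, but 8 splits are too few to judge. With at least 10 detected cells per library, a minimum chosen after the data were seen, 6 libraries entered, and 1 of 32 splits, the real one, reached 403 while the highest other gave 201, which argues against a grouping by chance in that fit.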

How the results depend on the processing

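All alternatives were planned except the 1000 UMI minimum, the highest UMI minimum, the minimum of 10 detected cells and those for the age effect in progenitors, which were added after the data were seen. Where a count moved, the cause was not tested.

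Leaving out each library in turn gave these ranges of called genes: stem cells 1543 to 3999 (P14 vs E18.5), 104 to 570 (adult vs P14) and 2457 to 3772 (adult vs E18.5); neuroblasts 450 to 1825 and 23 to 125 (adult vs P14); progenitors 1932 to 4656 and 33 to 424; Olig2-detected stem cells 184 to 784 and progenitors 893 to 1446; class shares P14 vs E18.5, 6 to 10. The lone library of an age was assumed to vary like the others. Olig2 in stem cells from E18.5 to adult ranged from −2.87 to 0.005, with the sign turned without adult replicate 2.

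The replicate block gave 834 genes in stem cells, 156 in neuroblasts and 579 in progenitors for adult vs P14; deviations of equally numbered libraries correlated by 0.098 to 0.235 between ages. DESeq2 gave 1833 (stem cells, P14 vs E18.5), 2513 (adult vs E18.5), 654 (neuroblasts, P14 vs E18.5), 670 (progenitors, adult vs P14), and 146 and 609 for Olig2 detection in stem cells and progenitors. Without the low-count filter, adult vs P14 gave 984, 446 and 1098 in stem cells, neuroblasts and progenitors, and the age effect 4 in stem cells and 301 in progenitors.

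With at most 5% mitochondrial UMIs the counts were 164 and 2076 in stem cells (adult vs P14 and vs E18.5), 424 and 17 in neuroblasts, 530 in progenitors (adult vs P14), 71 and 774 for Olig2 detection, and 2 classes for adult vs P14 shares. Leiden resolution 2.0 gave 3147 in neuroblasts (P14 vs E18.5) and 126 and 708 for Olig2 detection. Putting doublets back gave 534 in progenitors (adult vs P14). Cells thinned to 2000 UMIs gave 1381, 148 and 1790 in stem cells, 458 and 16 in neuroblasts, and 1784 and 21 in progenitors. The same number of cells per library gave 1809, 277 and 2554 in stem cells, and 282 and 23 in neuroblasts. The 1000 UMI minimum gave 2000 in neuroblasts (P14 vs E18.5) and 3 classes for adult vs P14 shares; the highest UMI minimum gave 272 in stem cells (adult vs P14) and 791 and 14 in neuroblasts.

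Without depth matching, Olig2 detection gave 4200 in progenitors and its age effect 243; with a minimum of 10 detected cells the age effect in stem cells gave 13. Thinning moved the Olig2 shares of stem cells to 18.98%, 10.44% and 5.94% from E18.5 to adult, and a threshold of 2 UMIs to 21.56%, 11.13% and 6.58%, lower by construction. Of 98 list calls, 9 held with an estimated correlation and 56 with fry. The minimum of 2000 UMIs removed no cell, and the minimum of 10 detected cells added no progenitor library, so neither tests anything there.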

Other observations

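At the finer clustering a small cluster stood apart by Olig2. It was named as stem cells, but scored 0.73 for both stem cell and astrocyte markers. It held 302 cells, 21 and 8 of them from the E18.5 libraries, and its leading genes included Egfr, Olig1, Dll1 and Olig2 itself; Olig2 stood at 373.4 CPM, beside 18.9 CPM in the larger postnatal stem cell cluster of 744 cells. At the coarser clustering, stem cell cluster 16 (E18.5) stood at 110.16 CPM and cluster 19 (postnatal) at 54.35. These clusters were picked after the values were seen.

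Haemoglobin RNA stood lower in Olig2-detected than in undetected stem cells, with Hbb-bt at −4.21 ± 0.21, Hbb-bs at −3.61 ± 0.30 and Hba-a1 at −3.19 ± 0.35 (log2 fold change ± SE, n = 4 libraries). The origin of this RNA was not tested. In dividing progenitors Hba-a1 stood at 1.15 ± 0.36, in the other direction but higher in only 4 of 6 pairs, a call (adjusted p = 0.0466) lost without E18.5 replicate 1 (0.0733), P14 replicate 1 (0.139), P14 replicate 2 (0.118) or adult replicate 1 (0.0672).

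A few genes with no known tie to cell type differed between P14 and adult in many classes. Hddc3 stood at 72.3 ± 15.7 CPM in P14 and 31.8 ± 3.72 in adult astrocytes and at 25.9 ± 12.8 and 5.72 ± 3.59 in microglia (unscaled CPM, SD, n = 2). Eif3j1 and its close relative Eif3j2 moved in opposite directions: in microglia Eif3j1 stood at 77.0 ± 14.2 and 24.4 ± 1.53, and Eif3j2 at 9.42 ± 2.56 and 23.1 ± 2.34. Barcodes with at most 100 UMIs held Hddc3 at 77.6 ± 6.01 at P14 and 29.3 ± 0.283 in the adult, Eif3j1 at 44.5 ± 0.311 and 26.6 ± 4.04, and Eif3j2 at 9.25 ± 0.539 and 14.1 ± 1.45, the same directions. Free RNA is therefore not excluded for Hddc3 in microglia. Microglia held more Eif3j1 at P14 (77.0 against 44.5) and more Eif3j2 in the adult (23.1 against 14.1) than those barcodes. These values argue against free RNA as the only source of Eif3j1 at P14 and Eif3j2 in the adult. No cause was tested for these.

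The number of postnatal stem cells depended strongly on the UMI minimum. With a minimum of 1000 UMIs in every library the class held 234 Olig2-detected and 1233 undetected cells in P14 replicate 1, beside 116 and 283 with the minimum used, and 139 and 1000 in P14 replicate 2, beside 41 and 136. In the adult the numbers were 23 and 188 beside 19 and 101 in replicate 1, and 31 and 647 beside 19 and 195 in replicate 2. At E18.5 the numbers were 253 and 309 beside 245 and 254 in replicate 1. The postnatal stem cells described in the report are therefore the RNA-rich part of the class in those libraries. Deeper analysis of the RNA-poor barcodes, with a model of free RNA, would be needed to say which of them are whole cells.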
